A study of Homo sapiens with 6 samples.

How the data were processed

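Ago2 binds microRNAs and the transcripts they pair with, so RNA recovered with an Ago2 antibody (the Ago2-IP fraction) was compared with RNA of the whole lysate (the total fraction) on 2-colour Agilent arrays. Per the labels' protocols, cells of a Hodgkin lymphoma line were transfected with 2.5 nmol of an anti-microRNA, the immunoprecipitation was done 16 hours later, and cRNA was amplified and labelled from 200 ng RNA. Anti-miR-17/20/93/106 was given to L1236 and to L428 cells, and anti-miR-220 to L428 cells only. Each of the 3 transfections was hybridised on 2 arrays with the dyes swapped, with Ago2-IP RNA in Cy5 on replicate 1 and in Cy3 on replicate 2. The labels describe the 2 arrays as dye swaps of 1 comparison, so their mean was counted as 1 replicate. They do not say whether both arrays carry the same RNA or RNA of separate transfections, so n = 1 for every transfection is the cautious reading, and the p-values over the 3 transfections measure the spread between these samples, 2 of which came from the same line.

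The arrays were read by the authors with Agilent Feature Extraction 9.1, per the submitters' processing notes. Per the file headers the deposited scanner files hold spot intensities, that is mean and background signals of the red and green channels that are not normalized, and processed signals that were background-subtracted and dye-normalized. The deposited value table holds log10 ratios. Set against the scanner values it equalled Feature Extraction's log10 of red over green, with the sign turned on replicate 2 (r = 1 or -1 on each array), so that it runs as Ago2-IP over total. Every column had a median of 0, and no further centring was found. The scanner files of the 2 L428 transfections and of L1236 carry different version numbers of Feature Extraction, and L1236 was scanned apart from L428. Each transfection had a slide of its own, so no slide held more than 1 transfection and the planned fit with the slide as a block was not run. Cell line and scanning batch cannot be told apart.

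Ratios were computed in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). Mean signals were corrected with normexp (offset 50), normalized within each array by loess (span 0.3, 4 iterations, control spots at weight 0) and turned to log2 Ago2-IP over total. Control spots and spots called outliers by the scanner software were left out, and spots of a probe were averaged. Of 41000 probes, 23434 were matched by RefSeq accession to a current symbol, which changed 4966 names, 2317 carried a current symbol already, and 15249 kept the identifier of the file. The 68 probes of XIST and Y-linked genes were left out. A gene was represented by its brightest probe. It was tested if that probe was well above background in 1 fraction on both arrays of at least 1 transfection, and if it had a value on all 6 arrays, which left 19019 of 19055 genes, 12193 of them with a current symbol. Of the 4849 genes with over 1 passing probe, 6 had probes both 2-fold or more lower and 2-fold or more higher. Probe positions are those given in the L1236 files, on hg17. Gene models of that build were not used here, so exons and untranslated regions are not stated.

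Depth here is signal over background, and the number of arrays limits the precision. Probes well above background numbered 22807 and 18014 in Ago2-IP and 22392 and 27408 in total for L1236. The L428 anti-miR-17/20/93/106 arrays had 24338 and 23702 in Ago2-IP and 23284 and 24319 in total. The L428 anti-miR-220 arrays had 21626 and 22209 in Ago2-IP and 20870 and 23440 in total. No spot was saturated. The median difference of a gene from the mean of its dye swaps was 0.10 in L1236, 0.10 in L428 with anti-miR-17/20/93/106 and 0.08 in L428 with anti-miR-220 (log2).

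Ago2-IP was compared with total over the 3 transfections with limma's moderated test of the mean ratio against 0 (2 residual degrees of freedom, 4.45 in all after moderation) and Benjamini-Hochberg adjustment. Fixed gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. With 1 replicate per group, single transfections and differences between transfections are values with no test. A gene was counted where the change reached 2-fold with the same sign in both dye orientations, among genes well above background in 1 fraction on both arrays of each transfection compared. A list's median was placed among 10000 random lists of the same size matched on mean signal (20 bins). Single channels for the L428 comparison were taken after loess and Aquantile normalization. Where 1 fraction was not well above background on both arrays, a gene's fold is a lower bound from single-channel means, the dim fraction being set at the higher of its own signal and the lowest signal of any probe well above background.

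The dye orientations were checked as pairs. The differences between dye swaps correlated across genes by 0.195, 0.158 and 0.711 for the 3 pairs of transfections, so the replicate numbers pair the arrays, as the labelled dyes do. With the replicate block (orientation as a term, transfection as a random block, correlation 0.711) 2597 genes were higher and 2406 lower in Ago2-IP at an adjusted p under 0.05.

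The genes named were chosen by a rule: for Ago2-IP against total the 15 highest and 10 lowest genes past the threshold with the same sign on all 6 arrays and well above background in both channels of all 6; for each difference between transfections the 15 at the lower and the 10 at the upper end for L428 and for L1236 minus L428, well above background in both channels of the 4 arrays; and up to 6 members of each list. Genes known only by a locus or reading frame name were passed over. A few genes that the rule chose are not reported here. Groups, lists, tests, this rule and most other settings tried were set before the data were examined. The 22 lists were written from general knowledge: reported targets of the miR-17 family, let-7, miR-155, miR-21 and miR-15/16, ribosomal proteins, ZNF zinc finger genes, replication-dependent histones, respiratory chain, proteasome, small RNA pathway, microRNA host transcripts, Hodgkin Reed-Sternberg markers, NF-kB targets, B cell program, T cell and natural killer markers, myeloid and stromal markers, G1/S cell cycle, BCL2 family and apoptosis, type I interferon response, TGF-beta signalling and housekeeping genes. The miR-17 list may include genes first reported from these samples, and is not independent evidence of a direction.

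A search for microRNA seed matches was planned in 3' untranslated regions, which were not used here. After the data had been seen, the 7-base sites were searched instead in the 60-base probe sequences of each gene, which cover only part of a transcript. Matching on untranslated region length and the choice of the transcript with the longest one were not run. Also chosen after the data were seen were a correction for the GC content of probes, runs without probes of 65% GC or more and without 2 single arrays, a list of immediate-early genes, and a ranking of 7-base words by the number of lowered genes holding them. The settings chosen beforehand were other background corrections and normalizations, the deposited value table, other filters, other thresholds, the mean over probes, single dye orientations and leaving out each transfection.

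The steps were tested on simulated data with an SD of 0.3 between transfections and 0.15 between arrays. Among 19019 genes, the test against total recovered 89 of 100 genes changed 2-fold and all 100 changed 4-fold, with 1 false call. For the L428 difference, all 200 changed genes of 16235 passed, and so did 395 genes with no set change. The spread of the L428 differences in the data was smaller than in that simulation, with an SD from the median absolute deviation of 0.26. By the same measure the differences between the lines had an SD of 0.58. The simulated transfections were independent and equally spread, unlike these, so the recovery and the 1 false call do not carry over to the data.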

Results

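RNA in the Ago2-IP fraction and in total lysate was measured on 6 arrays from 3 transfections of cultured Hodgkin lymphoma cells. L1236 and L428 are established lines derived from this B cell lymphoma, whose tumour cells are called Hodgkin Reed-Sternberg cells. Anti-miR-17/20/93/106 is an inhibitor directed at microRNAs that share the miR-17 seed, and anti-miR-220 served as the other anti-microRNA in L428. The arrays ask which transcripts are recovered with the Ago2 antibody above their share in total RNA. In L428 only, they also ask how this differs when the miR-17 family is inhibited. No control immunoprecipitation was among the arrays used here, so recovery unrelated to Ago2 cannot be told apart. Across 19019 genes, ratios of Ago2-IP over total correlated between the 2 L428 transfections by r = 0.916, and between L1236 and L428 by 0.568 with anti-miR-17/20/93/106 and 0.646 with anti-miR-220. Genes are not independent replicates, so these values describe likeness of profiles only.

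The genes highest in Ago2-IP were led by BTG2 and SOCS1. BTG2, an antiproliferative gene, had a mean log2 ratio of 4.04 ± 0.95 (SD, n = 3 transfections, as for the values that follow), and SOCS1, an inhibitor of cytokine signalling, 3.92 ± 0.55. ZFP36, which encodes an RNA-binding protein that promotes mRNA decay, had 3.31 ± 0.74, the kinase gene SGK1 3.30 ± 1.18 and the pseudokinase gene TRIB1 3.19 ± 0.81. The receptor gene TNFRSF12A (3.43 ± 0.53), the cell cycle genes CCNJ (3.18 ± 0.97), FAM83D (3.34 ± 0.74) and E2F7 (3.03 ± 0.72), and CFL2 (3.47 ± 0.73), BOD1 (3.45 ± 1.00), WIZ (3.17 ± 0.33), MMD (3.06 ± 0.69) and RHEBL1 (3.04 ± 0.95) were also among the 15 highest. All of these were higher in Ago2-IP on 6 of 6 arrays, with limma adjusted p between 0.0153 and 0.0228. The BTG2 probe lies on chromosome 1 at 200010111 to 200010170, that of SOCS1 on chromosome 16 at 11255885 to 11255944 and that of ZFP36 on chromosome 19 at 44591598 to 44591657 (hg17).

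At the lower end stood CRTC1 (-3.22 ± 0.61), HES7 (-3.13 ± 0.64), CDC42EP5 (-3.12 ± 0.61), HCN4 (-3.10 ± 0.69), PKN2 (-3.10 ± 0.66), COX6A2 (-3.09 ± 0.61), GPR153 (-3.08 ± 0.67), HS2ST1 (-3.07 ± 0.64), DUX4 (-3.06 ± 0.67) and FBXL17 (-3.05 ± 0.77), lower on 6 of 6 arrays with limma adjusted p of 0.0153 to 0.016. Of these 10 genes, 9 were measured by probes of 65% GC or more, as were 121 of the 196 genes at 4-fold or more lower. PKN2 turned to 1.95 with its other probe, when probes of 65% GC or more were left out, a run chosen after the data were seen. Among genes measured by probes of under 50% GC, a selection also made after their values were seen, the ribosomal protein genes RPL23A (-2.33 ± 0.64), RPL39 (-2.07 ± 0.62), RPL12 (-1.90 ± 0.42) and RPS29 (-1.76 ± 0.75), the histone gene H4C3 (-2.23 ± 1.16) and the transcription factor gene NFE2L1 (-2.17 ± 0.90) were among the 10 lowest.

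In all, 1677 genes were higher and 1570 lower in Ago2-IP at a limma adjusted p under 0.05, 770 and 598 of them by 2-fold or more. With the dye orientation as a term and the transfection as a block the counts were 2597 and 2406. These counts rest on the similarity of the L428 transfections. Without L1236, 4624 genes were higher and 4503 lower. Without L428 anti-miR-17/20/93/106 limma called 0 genes in either direction (4175 at an unadjusted p under 0.05), as it did without L428 anti-miR-220 (3569). With arrays centred on the median in place of loess it also called 0 (1956 at an unadjusted p under 0.05).

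Reported targets of several microRNAs were higher in Ago2-IP as groups with the preset correlation of camera. The lists overlap, so they are not separate results. CDC25A is on the let-7, miR-21 and miR-15/16 lists, WEE1 on those of miR-17, miR-155 and miR-15/16, and SOCS1 on those of let-7 and miR-155. BTG2, SOCS1 and MYC are also on the immediate-early list described below, and NF-kB and TGF-beta lists were higher too. Of 28 let-7 targets, 9 rose and 0 fell (12 and 0 adjusted over the list alone), among them the oncogene MYC (2.06 ± 0.34), DICER1 (1.75 ± 0.26) and CDC25A (1.75 ± 0.48), with a camera adjusted p = 0.00275 and an adjusted p = 0.762 with an estimated correlation. Of 17 miR-21 targets, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including BTG2, RECK (1.62 ± 0.83) and MARCKS (0.78 ± 0.06), with camera adjusted p = 0.00252 and adjusted p = 0.688 with an estimated correlation. Among 31 miR-155 targets 6 rose and 0 fell (10 and 0 adjusted over the list alone), with SOCS1, CEBPB (1.78 ± 0.53) and WEE1 (1.65 ± 0.51) among them (camera adjusted p = 0.0122, adjusted p = 0.835 with an estimated correlation). Among 19 miR-15/16 targets 7 rose and 0 fell (7 and 0 adjusted over the list alone), led by CCNE1 (2.04 ± 0.32) and DMTF1 (1.96 ± 0.79), with camera adjusted p = 0.0261 and adjusted p = 0.762 with an estimated correlation. Of 49 miR-17 family targets 9 rose and 4 fell (14 and 5 adjusted over the list alone). DNAJB9 (2.98 ± 1.05) and E2F3 (1.91 ± 0.27) rose, and STAT3 (-0.74 ± 0.13), E2F1 (-0.74 ± 0.30), ITCH (-0.59 ± 0.07) and MAP3K2 (-0.57 ± 0.14) fell. Its camera adjusted p was 0.0326, with an adjusted p = 0.835 with an estimated correlation. Without L1236 the camera adjusted p rose to 0.157 for the miR-17 list, 0.0833 for miR-155 and 0.0833 for miR-15/16, and with ratios corrected for probe GC to 0.144 for miR-17 and 0.0972 for miR-15/16.

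Ribosomal protein, housekeeping and histone lists were lower with the preset correlation of camera. Of 81 ribosomal protein genes 34 fell and 9 rose (48 and 13 adjusted over the list alone), with RPL13 at -2.62 ± 0.50 against RPL22 at 1.93 ± 0.42 and RPS24 at 1.38 ± 0.65 (camera adjusted p = 1.1e-05, adjusted p = 0.762 with an estimated correlation). Of 21 housekeeping genes 8 fell and 3 rose (11 and 4 adjusted over the list alone), with the glycolytic genes GAPDH at -2.30 ± 0.61 and ENO1 at -1.67 ± 0.36, and with TBP at 1.13 ± 0.40 in the other direction (camera adjusted p = 0.0326, adjusted p = 0.762 with an estimated correlation). Of 68 replication-dependent histone genes 7 fell and 3 rose, and none passed when adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.835 with an estimated correlation). The H4 genes H4C3 and H4C13 (-2.21 ± 1.21) were the lowest of the histones, and H3C1 (0.88 ± 0.16) and H3C6 (0.71 ± 0.19) rose. The histone call was lost without L428 anti-miR-17/20/93/106 (camera adjusted p = 0.255), without replicate 2 (0.0868) and with the GC correction (0.213). The housekeeping call was lost without L1236 (0.0833), without replicate 2 (0.0943), with median centring (0.0713), with processed signals (0.151) and with the deposited value table (0.152).

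**Figure D1:**
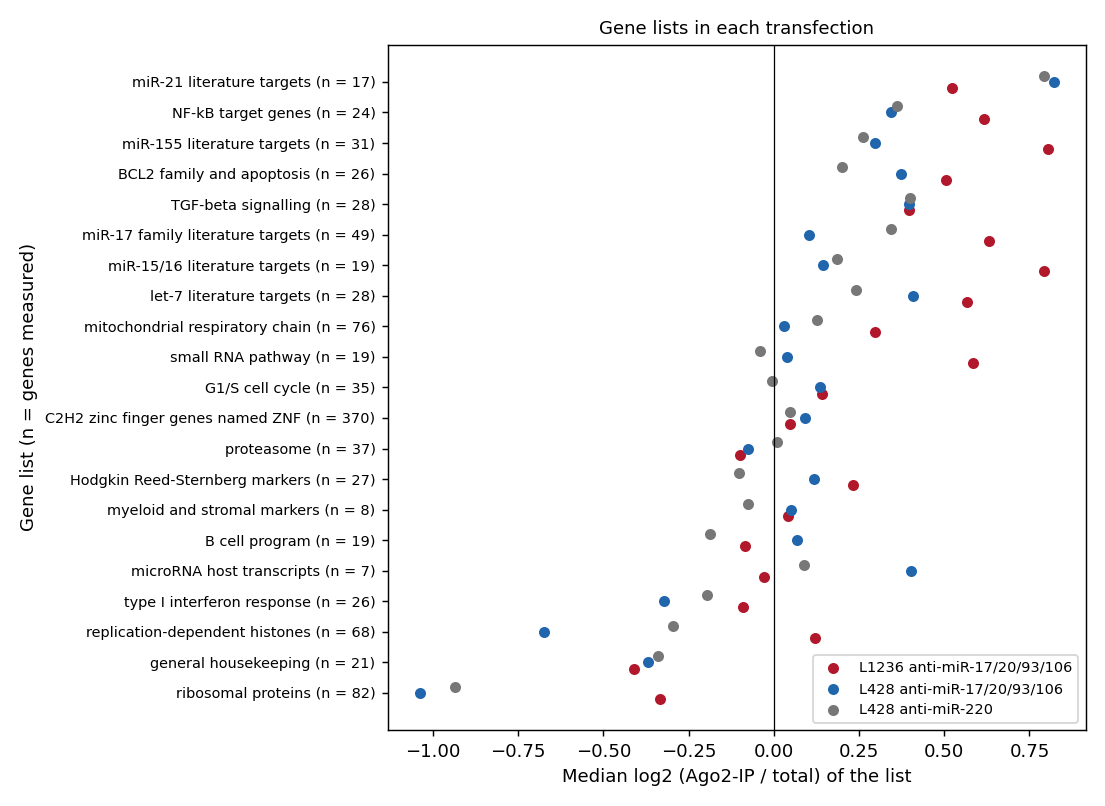
Median log2 ratio of Ago2-IP over total (x axis) for each gene list with at least 5 genes measured (y axis, number measured in brackets), with 1 point per transfection. Ribosomal protein genes lie below 0 in all 3 transfections, at -0.33 in L1236 and at -1.04 and -0.93 in L428 (with median centring 0.08 in L428 with anti-miR-17/20/93/106), and the miR-21 target list lies above 0 in all 3, between 0.52 and 0.82 (with median centring -0.004427 in L1236).

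In single transfections, 1432 genes were 2-fold or more higher and 585 lower in Ago2-IP of L1236, 1211 and 1233 in L428 with anti-miR-17/20/93/106, and 1156 and 1080 in L428 with anti-miR-220. The L428 transfections shared 839 higher genes (86.2 if independent) and 857 lower genes (81.4). L1236 shared 515 higher and 326 lower genes with L428 given the same inhibitor (102 and 44.7 if independent). In all 3 transfections, 430 of 14966 genes were higher and 311 lower. Among genes whose total signal was not well above background, CD69, a lymphocyte activation marker, was at least 5.62-fold higher in Ago2-IP of L1236, CPEB3 at least 2.84-fold higher in L428 with anti-miR-17/20/93/106, and LEFTY1 at least 2.21-fold higher in L428 with anti-miR-220. Conversely the complement receptor gene C3AR1, not well above background in Ago2-IP of L428 with anti-miR-220, was at least 2.47-fold lower there.

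Inhibition of the miR-17 family in L428 was compared with anti-miR-220 by the difference of the log2 ratios, given with the distance of each dye orientation from their mean. ZNFX1, a gene of an RNA helicase-like zinc finger protein, was lowest at -2.96 ± 0.07 (7.79-fold), having a ratio of 2.49 with anti-miR-220 and -0.47 with anti-miR-17/20/93/106. ZFYVE26 followed at -2.93 ± 0.14, the chemokine gene CCL1 at -2.23 ± 0.13, DDIAS at -2.08 ± 0.04, MIER2 at -2.01 ± 0.11 and the interferon-response transcription factor gene IRF9 at -1.89 ± 0.07. NABP1 (-1.75), GPR137B (-1.74), LIN7B (-1.73), NAGK (-1.59), PLEKHM1 (-1.55), S100A11 (-1.54), MTF1 (-1.53), GIT2 (-1.51) and the autophagy gene ATG16L1 (-1.44) completed the 15 lowest. The ZNFX1 probe lies on chromosome 20 at 47296463 to 47296522, that of ZFYVE26 on chromosome 14 at 67283035 to 67283094 and that of CCL1 on chromosome 17 at 29711722 to 29711781 (hg17). The highest were FOXK1 (1.56 ± 0.10), MED18 (1.44 ± 1.05), GINS4 (1.42 ± 0.20), TMEM184B (1.32 ± 0.13), NPBWR1 (1.32 ± 0.15), TAF5L (1.29 ± 0.24), SYNPO (1.28 ± 0.40), ACTBL2 (1.24 ± 0.31), IRF2BP2 (1.24 ± 0.09) and PIP5K1C (1.24 ± 0.57).

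**Figure D2:**
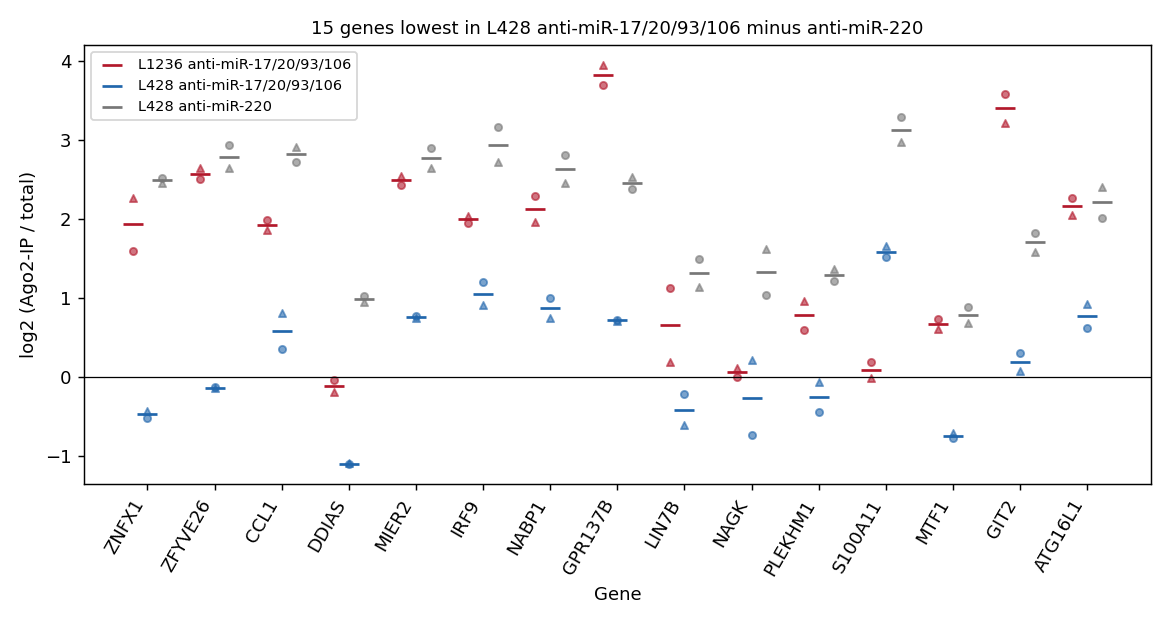
Log2 ratio of Ago2-IP over total (y axis) of the 15 genes lowest in L428 with anti-miR-17/20/93/106 against anti-miR-220 (x axis). Circles and triangles are the arrays of replicate 1 and replicate 2, and bars their mean, with 1 colour per transfection. ZNFX1 had 2.49 in L428 with anti-miR-220, -0.47 in L428 with anti-miR-17/20/93/106 and 1.93 in L1236 with anti-miR-17/20/93/106.

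Of 16235 genes compared, 69 were lower by 2-fold or more with anti-miR-17/20/93/106 and 71 higher. Of the 69, 35 were 2-fold or more enriched in Ago2-IP with anti-miR-220, and 6 with anti-miR-17/20/93/106, a contrast that choosing them by their difference builds in. Of all 1156 genes enriched 2-fold or more with anti-miR-220, 839 stayed so with anti-miR-17/20/93/106. In the single channels the 69 genes changed by a median of -0.96 in the Ago2-IP fraction and 0.33 in the total fraction, where 47 lay above 0. The medians of all 16235 genes were 0.02 and 0.05, and the choice of the 69 by their difference favours these signs. ZNFX1 changed by -2.11 in Ago2-IP and 0.85 in total, IRF9 by -1.46 and 0.43, and CCL1 by -0.45 and 1.78. The 71 higher genes, 30 of them with a current symbol against 56 of the 69, changed by a median of 0.84 in Ago2-IP and -0.35 in total. NPBWR1, SYNPO and PIP5K1C, however, changed by -0.92, -0.74 and -1.14 in Ago2-IP and by -2.24, -2.02 and -2.37 in total, a fall in both fractions. Their probes had 70, 71.7 and 63.3% GC and ratios of -2.01, -2.36 and -2.60 with anti-miR-220. These values may therefore share the behaviour of the depleted GC-rich probes. With 1 transfection each, no gene could be tested, and a simulation with a wider spread than these data gave 395 genes with no set change. The higher count was 132 without replicate 1 of both transfections, where the same sign in both orientations was no longer required. Replicate 1 of L428 with anti-miR-17/20/93/106 had a median signal of 560.5 in red against 95.02 in green. With median centring the median difference of all genes was 1.16, and 4 genes were lower and 9698 higher.

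Among the 47 miR-17 family targets compared, 7 were lower and 0 higher. These were ZNFX1, the TGF-beta pathway genes ZFYVE9 (-1.30 ± 0.11) and TGFBR2 (-1.02 ± 0.07), TXNIP (-1.24 ± 0.34), the autophagy genes SQSTM1 (-1.16 ± 0.08) and FYCO1 (-1.14 ± 0.08), and the glycolytic gene PFKP (-1.14 ± 0.05). The median of the list was -0.33, below all of 10000 random lists, and -0.31 without ZNFX1, again below all of them. Random lists treat genes as independent, so a place among them, here and below, is not a p-value. This list may include genes first reported from these samples, and leaving out ZNFX1 alone does not remove that limit. In the single channels the list changed by a median of -0.08 in the Ago2-IP fraction and 0.21 in the total fraction. All genes had 0.02 and 0.05 there, so the larger change of the list lay in the total fraction. With median centring the list median was 0.98, which lay 0.18 below the median of all genes. Other microRNA target lists had 1 or 0 lower genes, with medians of 0.11 for let-7 (percentile 97.4; 0.13 and 0.01 in the single dye orientations), -0.16 for miR-155 (1.31), -0.05 for miR-21 (28.0) and -0.04 for miR-15/16 (32.1). With median centring the miR-155 and miR-15/16 lists turned to 0.07 and 0.02 above all genes. Replication-dependent histones had 8 lower and 0 higher of 61 compared, with a median of -0.33 that lay below all random lists. All 8 were H4 genes, of 13 compared, from -1.35 for H4C8 to -1.01 for H4C2. Histone H4 genes are near-identical copies, although 3 of the 28 pairs of these probes share 20 bases or more in a row, so their values may not be separate. In the type I interferon list, with 1 lower gene, the median was -0.14 (percentile 2.64), and ribosomal protein genes had a median of -0.09 (percentile 0.01) with no gene past 2-fold, which was -0.01 in replicate 1 and -0.13 in replicate 2, and relative to all genes turned to 0.26 with median centring and 0.02 with processed signals. The 76 respiratory chain genes, none past 2-fold, had -0.09 (percentile 1.24), with 0.01 in replicate 1 and -0.18 in replicate 2. With median centring their median was 1.39, against 1.16 for all genes. At the upper end were the B cell program (median 0.24, percentile 99.4), ZNF zinc finger genes (0.05, percentile 99.9) and the BCL2 and apoptosis list (0.10, percentile 95.7; 0.24 in replicate 1 and -0.03 in replicate 2).

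Sites matching the miR-17 seed were searched in the probe sequences, as described above, chosen after the data were seen. The 137 compared genes with GCACTTT in a probe had a median difference 0.08 below that of genes without CACTTT (percentile 0.23), the lowest of 26 seed families, with -0.07 and -0.14 in the single dye orientations. The next was miR-155 at -0.06. By the planned measure, the median shift, GCACTTT ranked 93 of the 10055 words of 7 bases found in at least 50 genes. Ranked by the number of lowered genes above that expected, a measure added after the data were seen, it came 3 of 16381, with 7 lowered genes against 0.58 expected and 0 higher genes. LIN7B, CRY2 (-1.34), RHOC (-1.25) and FYCO1 were those with a current symbol. The shift of the site genes was 0.01 in the Ago2-IP fraction and 0.11 in the total fraction, and without replicate 1 these were -0.001909 and 0.0562. In Ago2-IP over total it was 0.07 in L428 with anti-miR-220 and -0.06 with anti-miR-17/20/93/106, and 0.07 in L1236 with anti-miR-17/20/93/106. The -0.06 turned to 0.15 with median centring and was -0.0160 without replicate 1, and the L1236 value was 0.0392 without replicate 1 and 0.0008732 with no filter on dim probes.

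**Figure D3:**
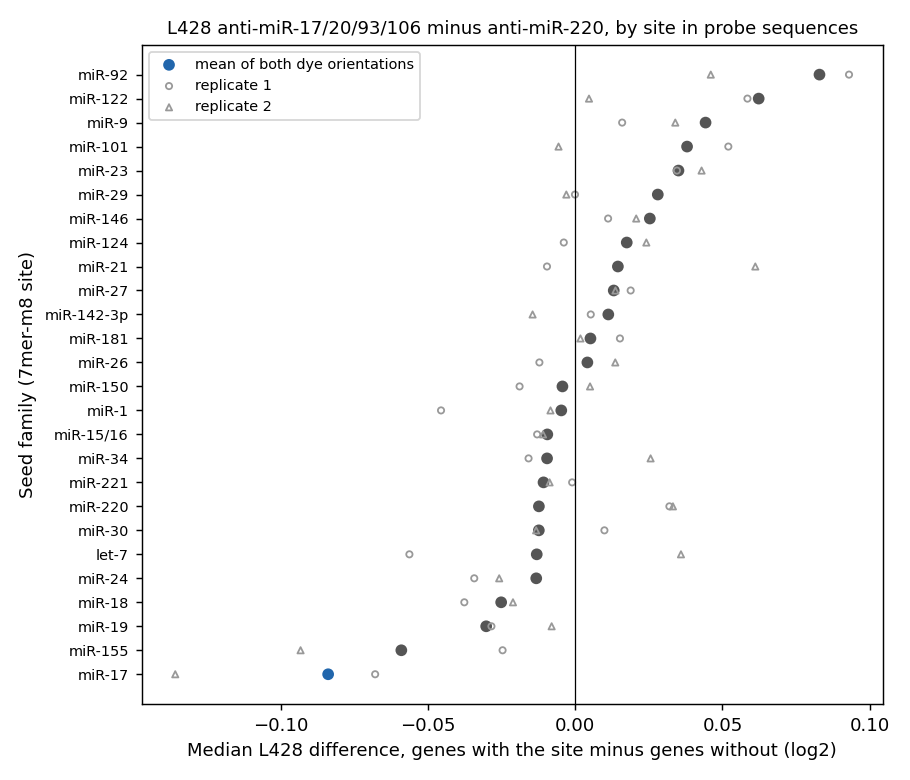
Median L428 difference (anti-miR-17/20/93/106 minus anti-miR-220, log2) of genes with a seed site in their probe sequences minus that of genes without it (x axis), for 26 seed families (y axis). Filled points are the mean of both dye orientations, blue for miR-17, and open symbols the single orientations. miR-17 has the lowest value, at -0.08, followed by miR-155 at -0.06, and miR-92 has the highest, at 0.08.

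Cell lines given the same inhibitor were compared as L1236 minus L428. BACH1, a transcriptional repressor gene, stood highest at 3.72 ± 0.11, with a ratio of 4.17 in L1236 and 0.45 in L428. It was followed by DET1 (3.51 ± 0.08), RAPGEF2 (3.32 ± 0.03), the translesion polymerase gene REV3L (3.29 ± 0.34), GIT2 (3.21 ± 0.07), NHLRC3 (3.11 ± 0.23), GPR137B (3.11 ± 0.14), the Polycomb cofactor gene JARID2 (3.06 ± 0.26), the small nucleolar RNA SNORA70 (3.02 ± 0.53) and the transcription factor gene MYB (2.96 ± 0.20). Among the lowest were the histone chaperone gene ANP32E (-2.67 ± 0.02), the chromatin protein gene HMGB1 (-2.53 ± 0.53), FOXK1 (-2.52 ± 0.01), ARLN (-2.52 ± 0.19), RAP1A (-2.51 ± 0.20), CLEC2D (-2.42 ± 0.11), EID1 (-2.41 ± 0.62), the spindle checkpoint gene MAD2L1 (-2.33 ± 0.35), SET (-2.28 ± 0.26), HNRNPK (-2.28 ± 0.32), ANP32D (-2.25 ± 0.22), HNRNPCL1 (-2.20 ± 0.40) and SDHC (-2.08 ± 0.03). ANP32D and HNRNPCL1 resemble other genes closely and their probes may have measured those. The BACH1 probe lies on chromosome 21 at 29639851 to 29639910 and that of ANP32E on chromosome 1 between 147016052 and 147017197 (hg17).

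By group, 12 of 28 miR-155 targets compared were higher in L1236 and 1 lower, with a median of 0.98 above all random lists, and among them BACH1, JARID2 and NFE2L2 (2.25). Of 49 miR-17 family targets 14 were higher and 2 lower (median 0.60, above all random lists), including ZNFX1 (2.40) and YES1 (2.38). Histones had 20 higher and 0 lower genes of 62 compared (median 0.76), respiratory chain genes 14 and 3 of 76 (median 0.56), and ribosomal protein genes 14 and 2 of 81 (median 0.59), but relative to the median of all genes the last 2 groups turned to -0.18 and -0.19 with median centring. There miR-155 targets lay 0.53, miR-17 family targets 0.30 and histones 0.33 above the median of all genes. In all, 1264 genes were higher and 801 lower of 15621. Both this difference and the L428 comparison use the L428 anti-miR-17/20/93/106 arrays, so values of ZNFX1, GIT2, GPR137B and FOXK1 in them are not separate. Of the 69 genes lowered in L428, 25 of the 64 compared were 2-fold or more enriched in L1236 with the same inhibitor, and no other transfection of L1236 was analysed here. The differences have no replicate check, cell line cannot be told apart from scanning batch or from serum (10% for L1236, 5% for L428), and with median centring 42 genes were higher and 9689 lower.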

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

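The test on the spike-in RNA was chosen after its values had been seen.

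Some values had opposite signs in the cell lines. They lay on 1 side of 0 on both L1236 arrays and on the other on all 4 L428 arrays, whichever inhibitor L428 had received, and the differences were not tested. Among gene groups this held for the replication-dependent histones, with a median difference per gene of 0.76 over the 62 compared. Their median over the 68 genes measured was 0.12 in L1236 and -0.68 in L428 with the same inhibitor. With median centring these signs turned round, to -0.76 in L1236 and 0.01 in L428. The medians of all genes then were -0.49 and 0.44. The 4 T cell and natural killer genes, too few to count as a group, also had opposite signs, with medians of 0.10 in L1236 and -0.21 and -0.33 in L428, but the L1236 median turned to -0.16 with the strict filter, -0.005971 with no filter and -0.06 with median centring. SNORA70 was higher in Ago2-IP of L1236 and lower in that of L428, with a difference of 3.02, as was MYB with 2.96. The opposite held for ANP32E (-2.67), HMGB1 (-2.53), ARLN (-2.52), RAP1A (-2.51), CLEC2D (-2.42), EID1 (-2.41), MAD2L1 (-2.33), SET (-2.28), ANP32D (-2.25), HNRNPCL1 (-2.20) and SDHC (-2.08). Genes named for the largest differences between the lines are those where such opposite signs are easiest to meet.

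Control spots for spike-in RNA, which entered no comparison, gave a signal far from 0 in L1236. Over 10 probes the mean log2 ratio of Ago2-IP over total was 4.94 ± 0.59 (SD over probes, 30.7-fold) in L1236, -1.92 ± 0.29 in L428 with anti-miR-17/20/93/106 and 0.55 ± 0.10 in L428 with anti-miR-220. If a fixed amount of spike-in had met less amplifiable RNA in the L1236 Ago2-IP sample, fewer probes would be well above background there. Over both dye orientations that number was 0.818 times the number in total in L1236, and 1.01 and 0.991 times in the L428 transfections. This rests on 1 array, because the number was 1.02 times that in total on replicate 1 of L1236 and 0.657 times on replicate 2, so a shortage stays undecided. The signal may equally reflect a different amount of spike-in given to the samples, which stays open, since the sources used here do not state how it was added and the negative value in L428 came with no surplus of probes. No biological explanation was tested.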

How the results depend on the processing

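Corrections for probe GC, runs without GC-rich probes or without 2 single arrays, random lists matched on the number of probes and the miR-17 list without ZNFX1 were chosen after the data were seen, as was the whole search in probe sequences.

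Limits came first from normalization. With median centring in place of loess the medians of whole transfections moved by up to 0.49, and the cause of the changes it made was not tested further. It gave 0 genes higher and 0 lower in Ago2-IP (limma, 1956 at an unadjusted p under 0.05), 442 higher and 4981 lower in L1236, 4756 and 329 in L428 with anti-miR-17/20/93/106, 363 and 3051 in L428 with anti-miR-220, 4 lower and 9698 higher in the L428 comparison, and 42 higher and 9689 lower in L1236 against L428. The miR-17 list turned to 0.98 and the site shift of L428 with anti-miR-17/20/93/106 to 0.15, with 0.0201 in L1236 and 0.0987 in L428 with anti-miR-220. Processed signals gave 157 lower and 156 higher genes in the L428 comparison, 1791 lower in L1236, 1919 higher and 1677 lower in L428 with anti-miR-220, 1588 lower in L1236 against L428, a list median of -0.41 and site shifts of 0.0569 in the Ago2-IP fraction, 0.15 in L1236 and 0.17 with anti-miR-220. The deposited value table gave 145 lower and 166 higher, 1836 higher in L428 with anti-miR-17/20/93/106, 1911 higher and 1688 lower with anti-miR-220, 1809 lower in L1236, 1657 lower in L1236 against L428, -0.39 for the list and shifts of 0.12 in L1236 and 0.17 with anti-miR-220. With offset 10 the list had -0.38 and the shifts were 0.10 in L1236 and 0.13 with anti-miR-220. The cause was not tested.

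Leaving out a transfection gave 0 to 4624 higher and 0 to 4503 lower genes in Ago2-IP (limma; 4175 and 3569 genes at an unadjusted p under 0.05 in the runs with 0), and 3 to 8 gene lists higher. Leaving out a replicate number or 1 of 2 single arrays gave 1 to 3 lists lower, 48 to 132 higher genes in the L428 comparison, a list median of -0.33 to -0.28, and site shifts of -0.136 to -0.0680 for the L428 difference, -0.0640 to -0.0160 with anti-miR-17/20/93/106, 0.0708 to 0.116 with anti-miR-220, -0.001909 to 0.0331 in the Ago2-IP fraction and 0.0562 to 0.139 in the total fraction. With the replicate block 2597 genes were higher and 2406 lower in Ago2-IP and 46 higher in the L428 comparison, and no other count moved by over 1.5 times. For differences between transfections, such as the 46, the transfection was a fixed term in that run, not a random block. Genes counted there reached 2-fold and a limma adjusted p under 0.05. The only spread behind that p is between dye swaps within single transfections. The 46 is therefore no test of a difference between the L428 transfections. camera with an estimated correlation called 0 lists higher and 0 lower. Correction for probe GC left 5 lists higher and -0.38 for the miR-17 list.

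At 1.5-fold, 297 genes were lower and 567 higher in the L428 comparison, and 3268 higher and 2120 lower in L1236 against L428. At 3-fold these were 12 and 0, and 277 and 160. The 8mer site gave shifts of -0.19 for the L428 difference, -0.11 in the Ago2-IP fraction, 0.19 in L1236, -0.003405 with anti-miR-17/20/93/106 and 0.30 with anti-miR-220. The 6mer site gave 0.0477 in the total fraction and 0.0111, -0.0230 and 0.0307 in the same 3 transfections. With no filter the shifts were 0.0289 in total, 0.0008732, -0.0223 and 0.0327, and the list had -0.24, while counts of single transfections did not move, because 0 of the 14377, 13593 and 14764 genes dim in both fractions of a transfection reached 2-fold, the largest log2 ratio being 0.97. The strict filter gave 0.15 with anti-miR-220. The mean over probes gave -0.24 for the list and shifts of 0.0707 in Ago2-IP, 0.0235 in L1236 and -0.0315 with anti-miR-17/20/93/106, and PKN2 at 0.24, against 1.95 without GC-rich probes.

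For the genes named from the ends of each comparison, members of lists not included, the direction held in 1111 of 1113 values under alternatives. PKN2 was the exception. Their call, or their value within its spread, held in 921. These genes were chosen with the same sign on all arrays, or for differences in both dye orientations. Runs that left out a replicate number, a single array or a transfection therefore could not turn the direction. Such runs are counted in the 1111 and do not test it.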

Other observations

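The tests for a single RNA species on GC-rich probes and for loess by median centring were chosen after their results were seen, and the immediate-early genes were listed after the most enriched genes had been seen. The other tests in this part were set before their results.

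Further gene lists were tested in Ago2-IP. NF-kB targets had 9 higher and 0 lower of 24 genes (11 and 0 adjusted over the list alone), with IER3 at 2.59 ± 0.39, the chemokine receptor gene CCR7 at 1.64 ± 0.50 and NFKBIA at 1.14 ± 0.32 (camera adjusted p = 0.00608, adjusted p = 0.762 with an estimated correlation). TGF-beta signalling had 6 higher and 0 lower of 28 (11 and 0 adjusted over the list alone), with TGIF1 at 1.64 ± 0.35 and SMAD7 at 1.04 ± 0.41 (camera adjusted p = 0.00399, adjusted p = 0.688 with an estimated correlation). In the BCL2 and apoptosis list 6 of 26 rose and 2 fell (6 and 3 adjusted over the list alone), the survival gene MCL1 rising (1.85 ± 0.25) and the pro-apoptotic genes BBC3 (-2.98 ± 0.52) and HRK (-1.91 ± 0.48) falling, with camera adjusted p = 0.0315 and adjusted p = 0.762 with an estimated correlation. This call was lost without L1236 (0.0833), without replicate 2 (0.0702), with median centring (0.144), processed signals (0.0547), the deposited value table (0.0518) and the GC correction (0.0851), and the NF-kB call without L1236 (0.0511). The median of the BCL2 and apoptosis list was 0.38, and 0.43 without probes of 65% GC or more, so some members had such probes. Whether BBC3 or HRK did is not stated here, and their values may share the behaviour of the depleted GC-rich probes. In the small RNA pathway 5 of 19 rose and 2 fell (5 and 4 adjusted over the list alone). The Ago partner genes TNRC6A (2.25 ± 0.24) and TNRC6C (1.90 ± 0.77) and DICER1 rose, AGO2 itself (-0.73 ± 0.28) and DGCR8 (-0.63 ± 0.14) fell, and the list had a camera adjusted p = 0.331, with its median turning from 0.17 to -0.11 with median centring. Of 35 G1/S genes 13 rose, led by CDKN1B (2.87 ± 0.75), and 6 fell, including CDT1 (-1.24 ± 0.25) and MCM4 (-0.86 ± 0.17), with 14 and 7 adjusted over the list alone, camera adjusted p = 0.352 and a median turning from 0.14 to -0.07 with median centring and to -0.003965 without replicate 2.

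Other lists had camera adjusted p above 0.05. Of 27 Reed-Sternberg markers 7 rose, with IL13 at 1.77 ± 0.57 and CD80 at 1.61 ± 0.70, and 2 fell, LTA and PWWP3A, the latter a different gene that an older use of the symbol MUM1 brought into the list (7 and 2 adjusted over the list alone, camera adjusted p = 0.581). Of 26 interferon response genes 2 rose, IRF9 (2.00 ± 0.94) and IFIT5 (1.19 ± 0.47), and 3 fell, with ISG15 at -1.21 ± 0.39 (4 and 7 adjusted over the list alone, camera adjusted p = 0.0883, and 0.0162 with no filter on dim probes). Of 76 respiratory chain genes 12 rose, with UQCRB at 1.93 ± 0.25, and 12 fell, with COX6A2 the lowest (22 and 16 adjusted over the list alone, camera adjusted p = 0.307). The COX6A2 probe had 55% GC, but its ratio lay among those of the depleted GC-rich probes. Of 37 proteasome genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.398; median -0.03, and 0.005679 with the GC correction), and of 369 ZNF zinc finger genes 41 rose and 21 fell (41 and 21 adjusted over the list alone, camera adjusted p = 0.213; median 0.09, and -0.05 with median centring). In the B cell program BCL6 (1.01 ± 0.17) rose, 1 of 19 with 0 lower and 1 and 0 adjusted over the list alone (camera adjusted p = 0.635), with a median turning from -0.09 to 0.03 with no filter and to 0.02 with the GC correction. Markers of other cell types were few, with 0 of 4 T cell and natural killer genes past the threshold in either direction, and COL1A1 (1.16 ± 0.36) the 1 of 8 myeloid and stromal genes that rose, both counts being unchanged when adjusted over the list alone (camera adjusted p = 0.365 and 0.999), and the median of the first turning from -0.13 to 0.0006907 with no filter. Among 7 microRNA host transcripts 0 rose and 1 fell, a probe still named TMEM49 (-0.81 ± 0.14), while a probe of the same locus named VMP1 had -0.15 ± 0.94 (3 and 1 adjusted over the list alone, camera adjusted p = 0.825).

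Most of the strongly depleted features were bright probes of 65% GC or more, and the 10 named genes had ratios close to each other within a transfection. An artefact of the loess fit was argued against by median centring in its place. The 121 genes with GC-rich probes at 4-fold or more lower then had a median of -2.97 (SD over genes 0.25, highest -2.15), against -2.84 with loess. The test set beforehand, with processed signals (-3.09 for the 10 named genes), decides nothing, since those signals are dye-normalized already. In 105 genes with both a GC-rich probe and another of 50% GC or less, the GC-rich probe was lower in 79. Over all 105 genes the median gap was -0.344 (SD over genes 1.25). It lies between the bounds set beforehand, -0.5 for hybridisation by GC content and -0.25 against it, and leaves that explanation undecided. In the 22 of these 105 genes picked because the GC-rich probe was 4-fold or more lower, a look taken afterwards, the other probe had a median of 0.08 and 1 was 2-fold or more lower. One RNA species hybridising to many such probes may account for part, since the 121 GC-rich genes differed between the cell lines with an SD of 0.253, 0.348 times that of genes matched on signal, though a shared response to GC content would also narrow it. No biological explanation was tested.

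Immediate-early genes, whose transcripts are short-lived, were common among the most enriched. As a hypothesis, such mRNAs may be enriched as a class. The test left out list members among the 30 most enriched genes, in any fixed list, among the named genes or among the genes lowered or raised in L428, all of which had been looked at. In the 27 that remained, 15 rose and 0 fell (limma adjusted p under 0.05), with medians of 0.84 in L1236, 1.04 in L428 with anti-miR-17/20/93/106 and 0.83 in L428 with anti-miR-220 (percentile 100 of random lists matched on signal in each). DUSP5 (2.34 ± 0.74), NR4A1 (1.89 ± 0.67), DUSP1 (1.89 ± 0.50) and EGR1 (1.88 ± 0.38) were the highest. Among those that did not pass were FOS (0.45 ± 0.39), JUN (0.41 ± 0.49), IER2 (0.16 ± 0.07), KLF6 (0.10 ± 0.09) and FOSB (-0.08 ± 0.11). The list was written by someone who had seen which genes led, and half-lives were not measured.

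For the count of genes in Ago2-IP against total, turning the sign of the ratios gave 4 patterns of the 3 transfections. Only 1 of 4 patterns, the real one, gave as many genes, 3247, and the highest of the others gave 0, but 4 patterns are too few for a share under 0.05.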
